A study of Mus musculus with 2 samples.

How the data were processed

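Mammary glands of CD1 mice were compared on the day the pups were weaned by force (day 0 of involution, the regression of the gland after lactation) and 1 day later. Per the labels, weaning took place at day 10 of lactation, litters had been set to 6 pups, and RNA of 5 mice was pooled for each day. Each pool was labelled with biotin and hybridised to 1 Affymetrix Mouse Genome 430 2.0 array, so the data are 2 arrays in 2 groups of 1. Pooling averages the mice before the measurement, and the spread between mice cannot be seen.

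The deposited values are MAS 5 signals, a probe set intensity on a linear scale, which the authors made with the statistical algorithms of the Affymetrix Microarray Suite 5.0, per the labels. The scaling target is not given in the sources used here. In the deposited values both arrays had a mean signal of 250 after 2% of the probe sets were trimmed at each end, so each array had been multiplied by 1 factor of its own. Detection calls and scanner images were not used here. A scaling of this kind holds the trimmed mean equal, which takes out a uniform difference in brightness between the arrays. A difference in background or RNA content that alters the trimmed mean is carried into every ratio.

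Of 45101 probe sets, 64 were Affymetrix controls. Of the other 45037, the platform annotation gave 34945 a single gene symbol and 932 several symbols, and 9160 were unnamed here. Symbols were updated through the gene identifier to those of the mouse RefSeq annotation of GRCm38.p6, which held the identifiers of 34741 of the 34945 probe sets. That table was used for names only, and no coordinates are given because no build is named for the array. Probe sets with several symbols were left out of all gene results. Of the unnamed probe sets, 3735 were measured, of which 154 were at least 2-fold higher and 637 at least 2-fold lower on day 1.

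All choices named as main were fixed before the data were examined. A floor of 77.7 signal units, the median of all signals of both arrays without the controls, replaced every lower value, and the ratio was log2 of the day 1 signal over the day 0 signal. A gene was measured if its brighter array was above the floor. A gene at the floor on 1 array has only a bound, written as "at least". For each gene the probe set with the highest mean signal was used. Probe sets of a gene were said to disagree when another measured one lay at least 0.5 log2 on the other side of 0, which held for 1118 of the 5672 genes with several measured probe sets. With 1 array per day there is no replicate error, and no test, p-value, SD or SE between days is possible. The number of arrays limits the precision. Over 3943 genes with several probe sets above the floor on both arrays, the log2 ratios of probe sets of the same gene had a pooled SD of 0.56, which describes differences between probe sets and not between mice.

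Genes were counted when the day 1 signal was at least 2-fold higher or lower. In addition, 18 process lists and 10 cell type marker lists were fixed. The median log2 ratio of each list was given as a percentile among 10000 random lists of the same size, matched on mean signal in 20 bins, and a list was said to stand apart below percentile 2.5 or above 97.5. By construction 5% of random lists stand apart. The percentile describes these 2 arrays and is not a test of the days. Of the measured list members, 12 genes belong to more than 1 list. The rule for named genes took the 12 largest differences in each direction above the floor on both arrays and the 4 largest bounds in each direction, leaving out genes with disagreeing probe sets and clone-type names. It also took the 4 members with the largest absolute ratio of each list, and Cldn1, Cldn3, Cldn4, Stat3, Socs3, Lif, Igfbp5, Stat5a, Wap, Csn2 and Lalba whatever their values. Control probe sets and their 3' to 5' signal ratios were read as deposited.

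Alternatives were median centring, quantile normalization, loess with a span of 0.3, scaling on the ribosomal protein or the housekeeping list, floors at the 25th and 75th percentile, no floor with a pseudocount of 16, the mean of all probe sets of a gene, leaving out probe sets shared between transcripts, thresholds of 1.5-fold and 3-fold, and random lists not matched on signal. Scaling on the hybridisation controls, and leaving out genes with a signal above 50% of the highest of an array, were added after the data were examined. A scaling can change which probe set of a gene has the highest mean signal, so each scaling was also run with the probe set of each gene held as in the deposited values, likewise added after the data were examined. On simulated data with noise of 0.25 log2 SD on each array, 50.0% of 200 genes changed 2-fold and 99.5% of 200 genes changed 4-fold were called. Of unchanged genes, 0.40% and 0.41% were called. The noise was chosen and not estimated from the data, where log2 ratios of probe sets of the same gene spread more widely (pooled SD 0.56). These shares check the steps and are not error rates of the 2-fold counts. Of 40 simulated lists of 20 genes, 0 stood apart without a shift and 40 with a shift of 1 log2. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.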

Results

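Gene expression was measured in mouse mammary gland at forced weaning (day 0) and 1 day later (day 1), with 1 array of RNA pooled from 5 mice for each day. The comparison asks which transcripts differ after the first day of involution. There were no replicate arrays, so every difference below is between 2 arrays and has no replicate check. Of 18193 named genes, 13239 were measured and 9768 were above the floor on both arrays. The median signal was 94.2 on day 0 and 60.1 on day 1, and 55.4% and 44.5% of the probe sets were above the floor.

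Spike-in controls were lower on the day 1 array. The 15 hybridisation control probe sets below 50% of the highest signal, bacterial transcripts added in equal amount to each hybridisation by the usual protocol, had a median log2 ratio of -1.16, with a range of -2.14 to -0.50. The 24 probe sets of polyadenylated bacterial controls had a median of -1.33. The highest signal was 108570 on day 0 and 40090 on day 1. The ratio of 3' to 5' signal was 2.5 on day 0 and 1.51 on day 1 for beta-actin, 1.52 and 1.48 for Gapdh, and 13.5 and 7.86 for pyruvate carboxylase. The log2 ratio of day 1 over day 0 was 0.20 at the 3' and 0.93 at the 5' probe set of beta-actin. It was -2.28 and -1.51 for pyruvate carboxylase, but 0.20 and 0.23 for Gapdh. Where a probe set lies in its transcript can thus alter its ratio, which limits ratios near 2-fold. Scaling on the hybridisation controls, chosen after these values were seen, raised the median log2 ratio of all measured genes by 1.10, so ratios below are best read against other genes.

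Pdk4, a kinase that inhibits pyruvate dehydrogenase, was 62.6-fold higher on day 1, with a signal of 7878.6 against 125.9. Angptl4, an inhibitor of lipoprotein lipase, was 46.4-fold higher and the tight junction protein gene Cldn4 38.8-fold higher. They were followed by Jpt1 (29.9-fold), Sbsn (26.9-fold), Basp1 (24.4-fold), Wfdc12 (20.4-fold), Rnase1 (18.4-fold), Krt7 (17.8-fold), Sox4 (16.4-fold), Dmkn (15.9-fold) and Hp (14.4-fold). Other probe sets of 3 of these genes had smaller ratios. The 7 of Sox4 ranged from -0.03 to 4.24 log2, both bounds, and the 3 of Sbsn from 1.92, a bound from a day 0 signal at the floor, to 4.75. The probe set used for Jpt1, with a day 0 signal of 100, had a log2 ratio of 4.90, and its other probe sets had 2.35 and 2.21. Day 0 signals of Dmkn (90.6) and Hp (113.2) were also just above the floor. In the other direction, Slc34a2, a sodium-phosphate cotransporter, was 145-fold lower, with a signal of 168.8 against 24556. G0s2, an inhibitor of adipose triglyceride lipase, was 43.2-fold lower, the chemokine gene Ccl28 24.3-fold and Olah, the thioesterase that releases medium-chain fatty acids, 22.4-fold. Chrdl2 had a log2 ratio of -4.91. Gldc (16.3-fold), Acacb (15.6-fold), Fkbp11 (15.5-fold), Egf (15.1-fold), Bhlha15 (13.3-fold), Fads2 (13.2-fold) and Insig1 (12.9-fold) were also lower. Dimmer probe sets of Fkbp11 and Bhlha15, at the floor on day 1, gave only bounds of -0.87 and -0.93 log2. The smallest differences among probe sets were -2.48 for Ccl28 and -2.50, a bound, for Fads2.

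Among genes at the floor on day 0, Cyp24a1, which encodes the vitamin D 24-hydroxylase, was at least 57.6-fold higher on day 1. Slc5a8 was at least 43.1-fold higher, and Cdkn1a, the cell cycle inhibitor p21, at least 25.9-fold. The dimmer probe sets of Cyp24a1 and Cdkn1a had log2 ratios of at least 4.03 and 3.12. Synpo was at least 25.8-fold higher, with signals of only 9.9 and 92.9 at its other probe set (at least 0.26 log2). Among genes at the floor on day 1, the calcium pump gene Atp2b2 was at least 57.2-fold lower, St6galnac1 at least 34.3-fold and Gnmt at least 19.8-fold. Lonp2 was at least 13.9-fold lower, but its other 2 probe sets had log2 ratios of -0.17 and -0.45.

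**Figure D1:**
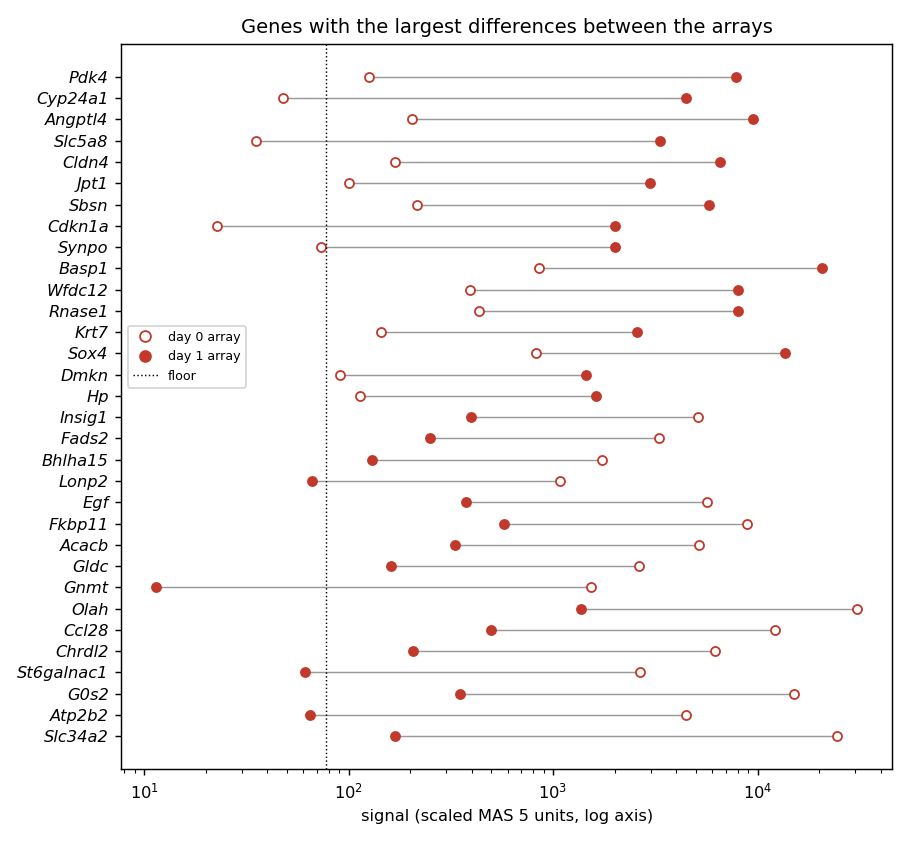
Signals of the genes with the largest differences on the day 0 array (open circles) and the day 1 array (filled circles), on a log axis in scaled MAS 5 units, with the floor of 77.7 as a dotted line. Slc34a2 has the lowest ratio, from 24556 to 168.8, and Pdk4 the highest among genes above the floor on both arrays, from 125.9 to 7878.6.

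In all, 1374 genes (10.4% of those measured) were at least 2-fold higher on day 1 and 1764 (13.3%) at least 2-fold lower. Of these, 244 were at the floor on day 0 and 682 at the floor on day 1, and the probe sets of 165 disagreed. At least 4-fold differences were seen in 259 genes with a higher and 242 with a lower signal, and at least 10-fold differences in 42 and 24. The balance depended on the scaling. Genes with a higher signal were 43.8% of those counted as deposited, 49.9% after quantile normalization, 57.9% after median centring, 58.0% after housekeeping scaling, 65.2% after loess, 72.6% after ribosomal protein scaling and 95.7% after hybridisation control scaling.

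Of the 28 fixed lists, 16 stood apart, 7 on the lower side and 9 on the higher side. Genes of milk fat synthesis and secretion were lower, with a median log2 ratio of -1.96, below all 10000 matched random lists, and 24 of 30 were at least 2-fold lower and 0 higher. Besides Olah and Fads2, the fatty acid binding protein gene Fabp3 was 10.9-fold lower, from a day 0 signal of 72791.9 near the top of the range, and Lpin1, a phosphatidate phosphatase, 9.63-fold lower. Genes of cholesterol synthesis had a median of -1.24, also below all random lists, with 11 of 20 at least 2-fold lower and 1 higher, and a median of 0.09 under hybridisation control scaling, or -0.075 with the probe set of each gene held. Insig1, a regulator of sterol synthesis, was followed by Mvd (5.22-fold lower), Stard4 (3.46-fold) and Pmvk (3.42-fold). The other 2 probe sets of Stard4 had log2 ratios of -0.51 and -1.11.

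Most milk protein genes were near the top of the signal range on both arrays. Their median log2 ratio was -1.25 (percentile 0.045), and 11 of 13 were at least 2-fold lower and 0 higher. The quartiles were -1.28 and -1.17, next to the -1.16 of the hybridisation controls. Of the 13 genes, 8 had a probe set above 50% of the highest signal on both arrays, where a signal may not follow the amount of RNA. Fabp3 and Cidea on day 0, and Basp1, Cd14 and Krt8 on day 1, were also above 50% of the highest signal, so their ratios share this limit. The same goes for the milk protein genes Ltf, Cel and Mfge8 on day 1. Wap was 2.38-fold lower, Csn2 2.54-fold, Glycam1 2.73-fold and Muc15 2.91-fold. Ltf (-0.39 log2) and Muc1 (-0.41), named after their values were seen, were under 2-fold. The brightest of 5 Csn1s2a probe sets was 2.43-fold lower, whereas 2 probe sets with day 0 signals of 27396.7 and 25978.9 were 15.5-fold and 11.8-fold lower; these 2 were singled out after their values were seen. After quantile normalization the milk protein median was -0.08, at percentile 36.8, and Lalba, 2.28-fold lower as deposited, was at 0.02 log2. This method gives both arrays the same distribution of signals, so genes among the brightest on both come out near 0 by construction. These values therefore cannot show whether milk protein transcripts fell.

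The lists of lactose synthesis, secretory cell transporters, prolactin and Stat5 signalling and oxidative phosphorylation also stood apart on the lower side, with medians above 0 under hybridisation control scaling (0.17, 0.32, 0.29 and 0.61). Lactose synthesis and glucose uptake had a median of -0.99 (percentile 0.13), with 4 of 9 genes at least 2-fold lower and 0 higher, among them B4galt1 (3.63-fold), Hk2 (2.96-fold) and Slc35a2 (2.68-fold, with a probe set at -0.73 log2). It did not stand apart after loess (percentile 3.63) or quantile normalization (percentile 5.52). The transporters had a median of -0.78 (percentile 0.08), with 9 of 18 at least 2-fold lower, including Slc34a2, Atp2b2 and Slc5a6 (4.67-fold), and 2 higher. The cotransporter gene Slc12a2 was 7.30-fold higher. With a floor at the 25th percentile or no floor the list was at percentiles 4.85 and 4.79.

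Of the genes of prolactin and Stat5 signalling, a pathway that maintains lactation, 5 of 13 were at least 2-fold lower and 0 higher. The list median was -0.82 (percentile 0.16). Stat5a was 3.19-fold lower, Akt1 2.75-fold, Socs2 2.36-fold and Igf2 2.15-fold, Igf2 with a log2 ratio of 0.06 under hybridisation control scaling. Another Socs2 probe set, above the floor on both arrays, had a log2 ratio of -0.79, and dimmer probe sets of Socs2 and Igf2, at the floor on day 1, gave bounds of -0.33 and -0.34. Oxidative phosphorylation genes had a median of -0.55 (percentile 0.16), with 5 of 35 at least 2-fold lower and 0 higher. The lowest were Ndufb5 (2.30-fold), Atp5g1 (2.21-fold), Uqcrc2 (2.15-fold) and Atp5o (2.11-fold), at -0.04, 0.02, 0.06 and 0.09 log2 under hybridisation control scaling with their probe sets held. Other probe sets of Ndufb5 and Uqcrc2 had log2 ratios of -0.60 and -0.84.

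Genes of Stat3 signalling and the acute phase, a pathway active at the onset of involution, were higher on day 1. Their median log2 ratio was 1.19, above all random lists, and 14 of 28 were at least 2-fold higher and 0 lower. Hp was followed by the serum amyloid genes Saa2 (13.5-fold) and Saa1 (12.4-fold), near-identical paralogs whose probes may not tell them apart, and by the oncostatin M receptor gene Osmr (12.9-fold), whose 3 probe sets ranged from -0.29, a bound, to 3.69 log2. Stat3 was 4.07-fold higher (probe sets from 0.54 to 2.03 log2), its feedback inhibitor Socs3 9.40-fold and Igfbp5, a binding protein of insulin-like growth factors, 6.57-fold. Lif, which activates Stat3, was at least 1.86-fold higher, with signals of 7.2 and 144.9. Immediate early genes had a median of 1.45, above all random lists, with 12 of 21 at least 2-fold higher and 0 lower, led by Gadd45b (13.8-fold), Klf6 (10.7-fold) and Jun (9.03-fold). Fosl2 was 5.79-fold higher with disagreeing probe sets, and other probe sets had log2 ratios of -0.36 for Gadd45b, at least 0.95 for Klf6 and 1.14 for Jun.

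Apoptosis and death receptor genes had a median of 0.49 (percentile 99.66), with 9 of 31 at least 2-fold higher and 2 lower. Tnfrsf12a, the receptor of the cytokine TWEAK, was 10.6-fold higher, and the proapoptotic genes Bid and Bik were at least 4.37-fold and at least 3.99-fold higher. Tnfrsf1b was 3.42-fold lower with disagreeing probe sets. Chemokines and cytokines had a median of 0.51 (percentile 99.96), with 9 of 29 at least 2-fold higher and 3 lower. Ccl9 was 8.37-fold higher, Ccl6 7.57-fold and Tgfb3 4.68-fold, in contrast to Ccl28. At a floor of the 75th percentile the list was at percentile 95.6.

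Tight junction genes had a median of 0.44 (percentile 99.45), with 8 of 25 at least 2-fold higher and 1 lower. Beside Cldn4, Cldn1 was at least 7.67-fold (at least 1.15 log2 at its other probe set) and Cldn3 7.43-fold higher, and Cldn8 was 4.80-fold lower. The list did not stand apart after loess (percentile 96.2), after quantile normalization (95.9), with a floor at the 25th percentile (91.7) or with no floor (86.7). Cell cycle genes had a median of 0.31 (percentile 99.21), with 5 of 18 at least 2-fold higher and 3 lower. The replication genes Mcm7 (3.94-fold), Mcm3 (at least 2.61-fold) and Pcna (2.16-fold) were higher, and the proliferation marker Mki67 was 7.27-fold lower. Another Mcm3 probe set had a log2 ratio of at least 0.25. Without probe sets shared between transcripts the cell cycle median was 0.01, at percentile 78.2, and it also lost its place apart in 3 other settings.

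**Figure D2:**
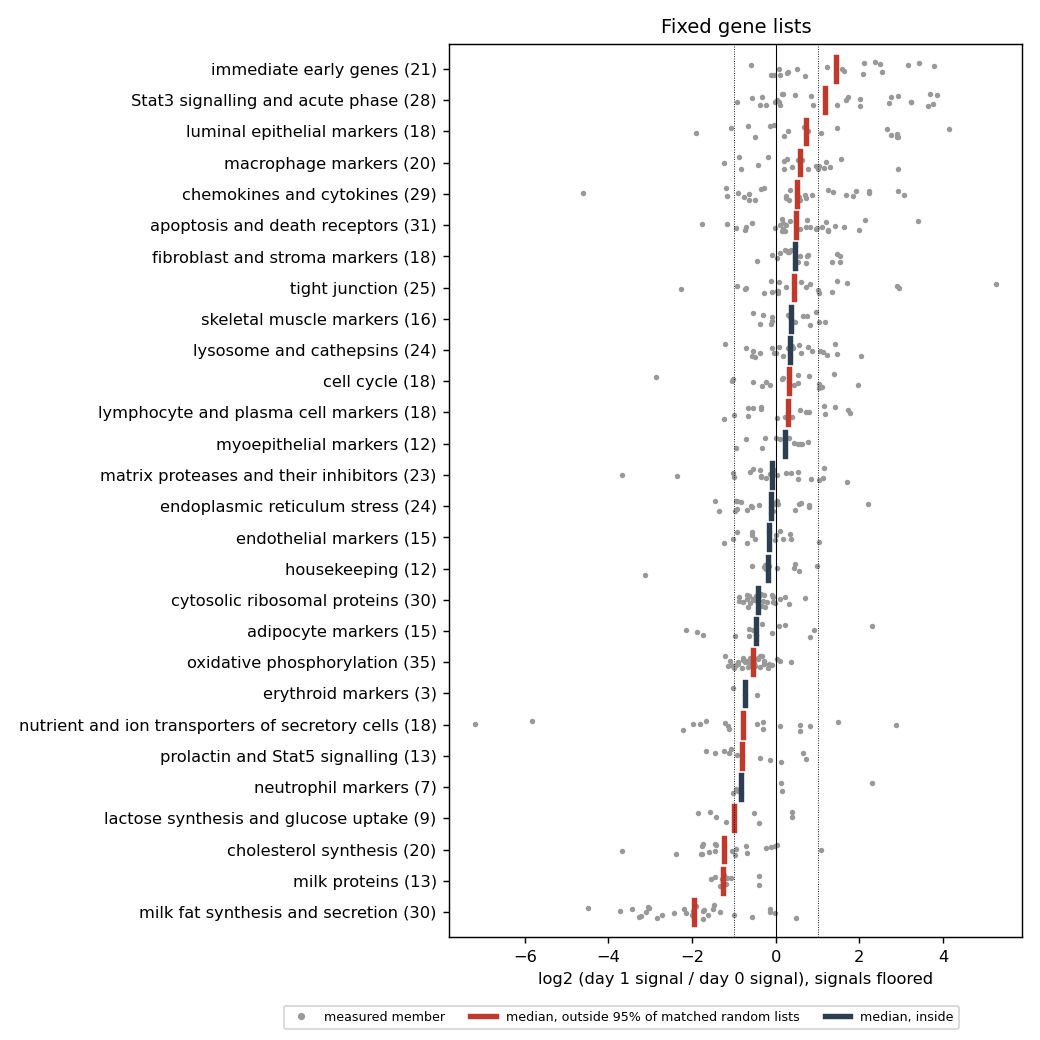
Log2 ratio of the day 1 over the day 0 signal for the measured members of each fixed list (grey points, number measured in parentheses) with the list median (bar), red where it lay outside 95% of matched random lists. Medians run from -1.96 for milk fat synthesis to 1.45 for immediate early genes. The hybridisation controls had a median of -1.16, and scaling on them turned the medians of lactose synthesis, transporters, prolactin and Stat5 signalling and oxidative phosphorylation above 0. The cholesterol synthesis median passed 0 under this scaling only when the probe set of each gene was not held.

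Among cell type markers, 3 lists stood apart, all on the higher side. Luminal epithelial markers had a median log2 ratio of 0.72 (percentile 99.78), with 8 of 18 at least 2-fold higher and 2 lower. The keratin genes Krt7, Krt19 (7.55-fold) and Krt8 (7.53-fold) led the list with Cldn3. Macrophage markers had a median of 0.58 (percentile 99.93), with 7 of 20 at least 2-fold higher and 1 lower. Cd14, which is also in the Stat3 list, was 7.60-fold higher, Cd68 2.94-fold and Arg1 2.47-fold, while the complement gene C1qa was 2.35-fold lower. Lymphocyte and plasma cell markers had a median of 0.30 (percentile 98.31), with 5 of 18 at least 2-fold higher and 2 lower, but a median of -0.11 with a floor at the 75th percentile. Ltb, Cd3g and Cd3d were at least 3.44-fold, 3.29-fold and 2.65-fold higher from day 0 signals at the floor, and Cd3e was 2.35-fold lower. The list did not stand apart in 6 further settings.

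The other 7 marker lists did not stand apart. Fibroblast and stroma markers had a median of 0.45 (percentile 95.67), with 4 of 18 at least 2-fold higher and 0 lower, including Thy1 (2.92-fold) and Mgp (2.91-fold). Skeletal muscle markers had a median of 0.36 (86.96), with 2 of 16 higher and 0 lower, and myoepithelial markers 0.22 (72.88), with 0 of 12 in either direction. Adipocyte markers had a median of -0.47 (percentile 5), with 1 of 15 higher and 3 lower. The 3 were Lpl, Cidea and Cd36, of which Lpl and Cd36 are also in the milk fat list. Endothelial markers had a median of -0.17 (29.54), with 1 of 15 higher and 2 lower. Neutrophil markers had a median of -0.83 over 7 measured genes (24.61), with 1 higher and 1 lower, and S100a8 was at least 4.97-fold higher. Erythroid markers had a median of -0.74 over 3 genes (8.78), with 1 lower and 0 higher. Under hybridisation control scaling the medians of the adipocyte, endothelial and neutrophil lists were 0.70, 0.99 and 0.33. The endothelial median was also above 0 after median centring (0.02), housekeeping (0.03) and ribosomal protein scaling (0.25), and the neutrophil median after loess (0.04) and quantile normalization (0.07).

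The remaining 5 process lists did not stand apart. Lysosomal genes had a median of 0.33 (percentile 95.58), with 6 of 24 at least 2-fold higher and 1 lower. Lgmn, a lysosomal protease, was 4.10-fold and Grn 2.78-fold higher, and Ctsc was 2.33-fold lower, with a bound of -0.36 log2 at a dim probe set. Matrix proteases and their inhibitors had a median of -0.09 (41.8), with 4 of 23 higher and 3 lower, and a median above 0 under 6 scalings (0.02 to 0.92). Adamts5 was 12.8-fold lower and Serpinb5 3.27-fold higher (probe sets from 0.53 to 1.71 log2). Endoplasmic reticulum stress genes had a median of -0.12 (17.66), with 1 of 24 higher, Chac1 (4.65-fold), and 2 lower. Cytosolic ribosomal protein genes had a median of -0.41 (4.6), with 0 of 30 at least 2-fold different, and housekeeping genes -0.19 (21.17), with 1 of 12 lower, Tfrc (8.68-fold), and 0 higher. Under hybridisation control scaling the last 3 medians were 1.05, 0.75 and 0.97. The stress median was also above 0 after median centring (0.07), housekeeping (0.07) and ribosomal protein scaling (0.30), and the housekeeping median after loess (0.04), quantile normalization (0.07), ribosomal protein scaling (0.22) and without shared probe sets (0.03).

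Some genes named above as at least 2-fold different were under 2-fold in other settings. Under hybridisation control scaling this held for Wap (-0.09 log2), Csn2 (-0.18), Csn1s2a (-0.12), Glycam1 (-0.29), Lalba (-0.03), Muc15 (-0.38), Pmvk (-0.61), Stard4 (-0.63 with its probe set held), B4galt1 (-0.70), Hk2 (-0.40), Slc35a2 (-0.26), Stat5a (-0.51), Akt1 (-0.30), Socs2 (-0.08), Tnfrsf1b (-0.61), C1qa (-0.07), Cd3e (-0.07), Ctsc (-0.06), Lpl (-0.98), Cidea (-0.71) and Cd36 (-0.59). Under ribosomal protein scaling it held for Wap (-0.84), Csn2 (-0.93), Csn1s2a (-0.87), Lalba (-0.78), Igf2 (-0.69), Socs2 (-0.83), C1qa (-0.82), Cd3e (-0.82), Ctsc (-0.81) and the 4 named oxidative phosphorylation genes. Median centring and housekeeping scaling did the same to Lalba, Igf2, Atp5g1, Uqcrc2 and Atp5o. After loess Wap (-0.65), Csn2 (-0.73), Csn1s2a (-0.62), Glycam1 (-0.77), Lalba (-0.57), Igf2 (-0.59) and Pcna (0.96) were under 2-fold, and after quantile normalization Wap (-0.08), Csn2 (-0.14), Csn1s2a (-0.03), Glycam1 (-0.09), Igf2 (-0.70) and Pcna (0.96). With a floor at the 75th percentile it held for Arg1 (0.09), Bid (0.44), Bik (0.31), Cd3g (0.03), Ltb (0.10), Cd3e (-0.13), S100a8 (0.63), Mgp (0.97), Pmvk (-0.80), Stard4 (-0.94), Slc5a6 (-0.75) and Tnfrsf1b (-0.22). With the mean of all probe sets it held for Mcm3 (0.82), Fosl2 (0.97), Igf2 (-0.72), Socs2 (-0.94), Ndufb5 (-0.90), Uqcrc2 (-0.97), Ctsc (-0.88) and Tnfrsf1b (-0.61). Igf2 was at -0.97 with no floor, and Lonp2 at -0.17 without shared probe sets. The milk protein values after quantile normalization were near 0 by construction, as said above.

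**Figure D3:**
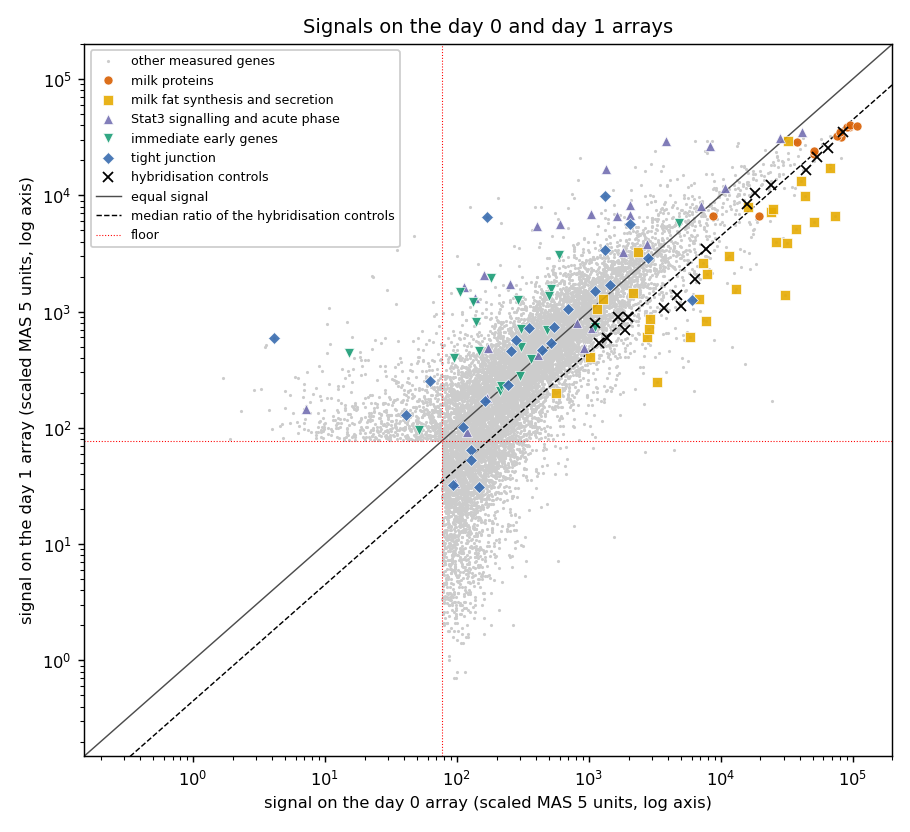
Signal of each measured gene on the day 1 array against the day 0 array, both on log axes in scaled MAS 5 units, with members of 5 fixed lists in colour, hybridisation controls as crosses and the floor of 77.7 as red dotted lines. The solid line marks equal signal and the dashed line the median log2 ratio of the hybridisation controls, -1.16. Most milk protein genes lie at the top right near the dashed line, and Ltf and Muc1 lie nearer the line of equal signal. The list median was -0.08 after quantile normalization, which brings genes among the brightest on both arrays near 0 by construction.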

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

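Scaling on the hybridisation controls, leaving out genes near the top of the range, and holding the probe set of each gene under the 6 scalings were chosen after the data were examined; the other alternatives were planned. No paired analysis was possible because there is 1 array per day, and for the same reason leaving out a replicate is not possible. Signals near the floor limit the genes given as bounds. They also limit genes just above it on 1 array, such as Dmkn (90.6), Jpt1 (100) and Hp (113.2) on day 0 and Igf2 (79.9) on day 1. Over the alternatives the lowest log2 ratios were 2.53 for Dmkn and 2.70 for Hp, against 3.99 and 3.85 as deposited. Signals near the top of the range limit the milk proteins and Fabp3, Cidea, Basp1, Cd14 and Krt8. Except for a change of probe set, the cause of each change below was not tested. Milk fat synthesis was below all random lists, and Stat3 signalling and immediate early genes were above all, in each setting run; the apoptosis, macrophage and luminal lists also stood apart in each setting on the same side. Of 1604 values of single named genes under the alternatives without held probe sets, 1442 kept their side of the 2-fold threshold, 116 no longer passed it, 37 newly passed it, and 9 that were at least 2-fold as deposited changed sign, 3 of them because another probe set was taken. A further 12 sign changes were of values under 2-fold as deposited, 2 of them with another probe set.

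The count of genes at least 2-fold higher (1374) became 852 with a floor at the 75th percentile, 2209 after loess, 2648 after ribosomal protein scaling and 6398 after hybridisation control scaling, and the count lower (1764) became 606, 1177, 999 and 285. With the probe sets held, the counts were 1835 higher and 1182 lower after loess, 2619 and 1008 after ribosomal protein scaling and 6292 and 295 after hybridisation control scaling. The count lower was 4306 with a floor at the 25th percentile and 4098 with no floor. At 1.5-fold there were 2699 higher and 3601 lower, and at 3-fold 510 and 573. Without genes near the top of the range there were 1363 and 1747. The median of all genes moved by 1.10 log2 under hybridisation control scaling, 0.39 under ribosomal protein scaling, 0.31 under loess, 0.18 with the floor at the 75th percentile and 0.16 under both median centring and housekeeping scaling.

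Under hybridisation control scaling the list medians of cholesterol synthesis (0.087, but -0.075 with the probe sets held), lactose synthesis (0.17), transporters (0.32), prolactin and Stat5 signalling (0.29) and oxidative phosphorylation (0.61) were above 0, with percentiles of at most 0.13, and cell cycle (1.02) and lymphocyte markers (1.14) no longer stood apart. Atp5g1 (0.019), Atp5o (0.086), Igf2 (0.056), Kdr (0.15) and Uqcrc2 (0.058), all at least 2-fold lower as deposited, changed sign. Lonp2 (0.99), Ndufb5 (0.56) and Stard4 (0.053) did so only because another probe set became the brightest; the probe sets used as deposited were at -2.86, -0.041 and -0.63. Under the other scalings that take another probe set for Stard4, it stayed at least 2-fold lower with its probe set held. The other list results given here kept their sign, and stood apart or not, with the probe sets held. Too few erythroid genes were measured for a value under hybridisation control scaling, with a floor at the 75th percentile, without shared probe sets, or after loess with the probe sets held, and the same goes for neutrophil genes with a floor at the 75th percentile and milk proteins without genes near the top of the range. After quantile normalization Lalba changed sign (0.020), milk proteins (-0.078), lactose synthesis (-0.48) and tight junction (0.35) no longer stood apart, and stroma markers did (0.49). The values of Lalba and the milk proteins were near 0 by construction, because these genes are among the brightest on both arrays. After loess lactose synthesis (-0.57), tight junction (0.34) and lymphocyte markers (0.46) no longer stood apart, and stroma markers did (0.52).

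Lymphocyte markers also no longer stood apart after median centring (0.45), housekeeping scaling (0.45) and ribosomal protein scaling (0.62), and changed sign with a floor at the 75th percentile (-0.11), where cell cycle (0.35) and chemokines (0.28) no longer stood apart. With a floor at the 25th percentile this held for transporters (-0.38) and tight junction (0.16), and with no floor for transporters (-0.37) and tight junction (0.063), while ribosomal proteins stood apart (-0.42). Without shared probe sets cell cycle no longer stood apart (0.0079) and stroma markers did (0.59). Against random lists not matched on signal, cell cycle (0.31) and lymphocyte markers (0.30) no longer stood apart, and the lysosome (0.33), neutrophil (-0.83), stroma (0.45) and skeletal muscle (0.36) lists did.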

Other observations

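All tests in this part were chosen after the values were seen, and so were the gene families. When genes were grouped by the stem of their symbol, 12 of 316 families stood apart from matched random lists on the higher side and 13 on the lower side. Random lists would give 7.9 on each side, so a large part of these families may be there by chance. The families below were picked from this scan. All settings use the same 2 arrays, so a percentile that holds over them is not independent support. The annexin genes, which encode calcium-dependent membrane-binding proteins, were among the highest. All 8 measured annexin genes were at least 2-fold higher on day 1, with a median log2 ratio of 2.01 and percentiles of 99.94 to 100 over the 19 settings run. Anxa3 was 13.4-fold, Anxa1 12.1-fold and Anxa5 4.42-fold higher. The 14 Psmd genes, of the regulatory part of the proteasome, had a median of 1.01 with 7 at least 2-fold higher and 0 lower, a median of 0.52 with the mean of all probe sets, and percentiles of 98.61 to 100. The 7 Itgb integrin genes had a median of 1.17, with 4 at least 2-fold higher and 0 lower, 57.1% above 0, and percentiles of 94.25 to 99.97. On the lower side, the 39 Slc25a mitochondrial carrier genes had a median of -0.52, which was 0.65 under hybridisation control scaling, with 9 at least 2-fold lower and 4 higher, and percentiles of 0.13 to 2.03.

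The brightest milk protein probe sets were lower on day 1 by nearly the same factor, and 2 explanations were tried. A ceiling on both arrays, scaled by different factors, would hide larger differences at the brightest probe sets. The 3 dimmer probe sets of Csn1s2a and Csn3 that were above the floor on both arrays had log2 ratios lower than the brightest probe set of their gene by a median difference of -2.28, as a ceiling would give, but 2 genes are too few to decide, a dim Csn1s2a probe set at the floor on day 1 (a bound of -0.60) was left out, and the probe sets may read different transcript ends. A fall of milk transcripts was read from the 6 milk protein probe sets below 50% of the highest signal, with a median of -1.72 and quartiles of -3.15 and -0.84. They come from only 4 genes, several from Csn1s2a, and the bound of -0.60 was counted among them as a value. A first cutoff at 12.5% had left 2 probe sets, that bound and 1 of Csn3 (-1.90), and the wider cutoff was chosen after that. Their median of -1.25 is near the control ratio of -1.16. A decision needed 3 probe sets at each cutoff, so a fall stays open. The small spread of the 17 probe sets above 50% of the highest signal on both arrays (SD 0.24) was not used, because that selection alone confines their log2 ratio to between -2.44 and -0.44.

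Control probe sets were lower on day 1, and again 2 explanations were tried. Less of the hybridisation control mix on the day 1 array would leave other quantities level, but the 10th percentile of all signals was also lower, at -0.97 log2, as were the polyadenylated controls, at -1.33, which come from another mix. This argues against that mix as the whole cause. A larger share of milk transcripts in the day 0 RNA could raise the scaling factor of that array. The dimmer milk protein probe sets had a median of -0.56 against the hybridisation controls at the 50% cutoff and -0.09 at the 12.5% cutoff. The latter rests on 2 probe sets, of which that of Csn1s2a was at the floor on day 1 and gives only a bound. With so few probe sets this explanation stays open. Total RNA and scanner settings were not analysed here, and with 1 array per day an array effect and the day cannot be told apart.

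The 6 keratins and claudins of the luminal list were higher on day 1. This does not hold for the Krt family as a whole, whose 25 measured genes had a median of -0.69 (percentile 0.65), with 5 at least 2-fold higher and 9 lower. The 5 higher genes were Krt80 and the luminal list keratins Krt18, Krt8, Krt19 and Krt7. The other members are not in the luminal list, and Krt5, Krt14 and Krt17 are in the myoepithelial list. The family median therefore does not speak to luminal cells. With a floor at the 75th percentile the Krt median was -0.29 (6.83), not standing apart. Under hybridisation control scaling it was -0.035 (0.01). The 14 Cldn genes had a median of -0.017 (percentile 83.25), which was 1.25 (99.86), standing apart, with a floor at the 75th percentile, 1.15 (95.97) under hybridisation control scaling and 0.17 (95.26) with the mean of all probe sets. A larger share of luminal epithelial cells would raise the other luminal markers as well, but these 12 genes had a median log2 ratio of 0.083 with quartiles of -0.54 and 0.70, against a median of 2.90 and a lower quartile of 2.72 for the 6 keratins and claudins of the list. The 6 genes were set apart after their values were seen, and most of those leading the list are among them. Such a split favours a gap, so the comparison cannot decide on a larger luminal share. It shows only that the other 12 markers did not rise as the 6 did. A change of expression within luminal cells stays open as a hypothesis and was not tested.

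The macrophage list was also set against 4 other marker lists, and is given as values only. The endothelial and adipocyte medians (-0.17 and -0.47) lay below the macrophage lower quartile of 0.10, and the myoepithelial and stroma medians (0.22 and 0.45) did not. The upper quartiles of the endothelial and adipocyte lists, 0.13 and 0.15, overlapped the macrophage quartiles.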
